A study of Mus musculus with 12 samples.

How the data were processed

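RNA was sequenced from EMT6 cells, a mouse breast cancer line, in a design of 2 factors. A subclone with ISG20 knocked down by a short hairpin RNA (shISG20) and a control subclone (shNTC) were each kept at 20% O2 or 1% O2 for 48 hours, per the labels' protocols. Each of the 4 groups held 3 libraries that the labels call biological replicates, 12 in all. The label of shISG20 replicate 3 at 20% O2 gives 484 hours in place of 48, and the library was kept in its group. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical in part. Total RNA was extracted with TRIzol and treated with DNase before sequencing, per the labels' protocols.

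The authors deposited a table of transcripts-per-million values (TPM) with 60683 rows, and no other measurement was analysed here. FastQC, STAR, featureCounts and the build GRCh38 were used, per the submitters' processing notes, and versions and the step from counts to TPM were not given in the sources used here. GRCh38 is a human build and the rows are human Ensembl genes, although the cells are mouse. Reads could therefore be counted where they were close enough to a human gene to align. Levels cannot be compared between genes, diverged genes sit near 0, and a gene listed at 0 may be a gene whose mouse reads did not align. Symbols are given as in the table. Coordinates are left out, because the mouse reference used here for gene names, GRCm38, is another build than that of the table.

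In all, 40392 rows (66.6%) were at 0 in every library. Rows with at least 1 TPM in at least 3 of the 12 libraries were tested, which left 14389. Of these, 8337 carried the symbol of a mouse gene, 251 a mouse synonym, 3588 the name of a pseudogene, 1661 no name and 552 another name. Pseudogene rows held 33.5 to 37.0% of the TPM of a library and 9.38 to 12.4% of its reads. Rows that matched a mouse gene held 45.6 to 49.1% of the TPM and 82.7 to 86.3% of the reads. A pseudogene row can share reads with the gene it is named after, so levels of genes with many such copies, ribosomal protein genes and GAPDH among them, are uncertain.

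TPM keeps no depth by itself. The ratios of a row between libraries were ratios of whole numbers for 100% of the values above 0 (tolerance 0.01, largest deviation 2.6e-10), so the reads behind each value were recovered up to a common divisor per row. They summed to 3173991 to 5201799 reads per library. Read numbers printed beside a gene are these recovered reads, summed over the 3 libraries of a group.

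Tests were run in R 4.3.3 with limma 3.58.1 on log2(TPM + 1), with empirical Bayes moderation and a trend of the variance on the mean. All 12 libraries entered a single fit with 1 coefficient per group and no covariate. Adjusted p-values of genes are Benjamini-Hochberg values over the 14389 rows of a comparison, with a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Errors of TPM levels are standard deviations (SD) over n = 3 libraries, and errors of log2 fold changes are limma's standard errors (SE). Files were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

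The design, the rule for named genes, 21 gene lists and the alternatives below, except where stated, were fixed before the data were examined. The rule took ISG20, HIF1A, EPAS1 and ARNT, and per comparison the 10 highest and the 10 lowest log2 fold changes among called genes with at least 5 TPM in the higher group and no overlap between the libraries of the groups compared. The overlap condition was left out for the interaction. The rule also took up to 4 called members of each gene list with the smallest p, or the 2 most abundant members of a list without a called member. It passed over rows without a proper gene name, which was read here as rows that matched no mouse gene, 1 to 19 per comparison and direction. Genes named outside this rule are marked as such, and some genes that the rule took are not reported here.

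The lists covered glycolysis and glucose uptake, other targets of hypoxia-inducible factor (HIF), interferon-stimulated genes, nucleic acid sensing, antigen presentation by MHC class I, chemokines and cytokines, immune checkpoints and the adenosine pathway, DNA replication and S phase, mitosis, nuclear genes of oxidative phosphorylation, genes of the mitochondrial genome, cholesterol synthesis, the unfolded protein and integrated stress responses, p53 targets, extracellular matrix and collagen, epithelial-mesenchymal transition markers, RNA decay and 3' to 5' exonucleases, cytosolic ribosomal proteins, replication-dependent histones, markers of leucocytes, and markers of endothelial cells and fibroblasts. Coverage was uneven: 15 of 45 interferon-stimulated genes, 9 of 36 chemokines and cytokines, 1 of 17 leucocyte markers, 1 of 13 mitochondrial genome genes and 3 of 14 endothelial and fibroblast markers could be tested, against 40 of 40 ribosomal protein genes and 26 of 28 S phase genes. COL3A1 stands in both the matrix list and the list of fibroblast markers. Lists were tested with limma's camera at an inter-gene correlation preset to 0.01, which compares a list with all other rows. The test was repeated with an estimated correlation and with fry, which asks whether a list's genes move one way on balance without comparing them with others. Adjusted p-values of lists are Benjamini-Hochberg values over the 19 lists with at least 3 tested members.

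The fit was tested on simulated data made from the recovered reads (dispersion 0.00166), with 200 genes changed per comparison. At 20% O2, 19, 26, 35 and 42 of 50 genes changed by 1.5, 2, 4 and 8 times were recovered among 13960 rows, with 5 false calls among 127. At 1% O2 these numbers were 18, 29, 34 and 47 among 13991 rows, with 8 false calls among 136. For hypoxia in shNTC cells they were 21, 35, 34 and 41 among 13983 rows, with 12 false calls among 143, and in shISG20 cells 19, 28, 37 and 40 among 13982 rows, with 13 false calls among 137. For the interaction they were 8, 24, 36 and 40 among 13977 rows, with 7 false calls among 115. In a simulation at 20% O2 camera called the 1 changed and 0 of 20 unchanged lists, but correlated genes were not tested.

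Alternatives were pseudocounts of 0.1 and 3, no filter, a mean of at least 5 TPM, quantile normalization, median-of-ratios size factors, rescaling without the 50 most abundant and the mitochondrial genes, the replicate number as a block, only the groups compared, no variance trend, library quality weights, a log2 fold change of at least 1, and each library left out in turn. Voom on the recovered reads and a fit of rows that match a mouse gene alone were added after the data were seen. Count models planned for a table of counts were not run, because the table holds TPM. Replicates were compared before they were averaged: the chi-square per degree of freedom of their recovered reads was 1.33 to 2.31 in the 12 pairs within a group, above sampling noise in each, and the correlation of log2 values across genes was 0.967 to 0.977.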

Results

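Gene expression was measured by RNA sequencing in EMT6 mouse breast cancer cells of a control subclone (shNTC) and of a subclone with ISG20 knocked down (shISG20), each at 20% O2 and at 1% O2, with 3 libraries per group. The recovered depth was 3413952 to 3745276 reads per library in shNTC cells at 20% O2, 3520400 to 4765241 in shNTC cells at 1% O2, 3251090 to 5201799 in shISG20 cells at 20% O2 and 3173991 to 3779498 in shISG20 cells at 1% O2. Between 12479 and 13468 rows per library reached 1 TPM. The first principal component held 54% of the variance and separated the oxygen levels, and the second held 8.2% and separated the subclones. The row with the most TPM was RPS12, a ribosomal protein gene, in the libraries at 20% O2 (1.07 to 1.23%) and TMSB10, an actin-binding thymosin, in those at 1% O2 (2.55 to 2.75%). The question of the series was how loss of ISG20 changes expression. With a single knockdown subclone and a single control subclone, an effect of the knockdown and a difference between subclones cannot be told apart in any comparison between them.

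ISG20 (ENSG00000172183), an interferon-induced 3' to 5' exonuclease, was lower in the shISG20 libraries at both oxygen levels. At 20% O2 it stood at 2.46 ± 0.372 TPM (SD, n = 3; 75 reads) in shNTC cells and at 0.225 ± 0.0942 TPM (7 reads) in shISG20 cells, a log2 fold change of -1.496 (SE 0.159, limma adjusted p = 0.000228). At 1% O2 it stood at 8.28 ± 0.623 TPM (334 reads) against 0.566 ± 0.14 TPM (19 reads), a log2 fold change of -2.57 (SE 0.159, adjusted p = 1.09e-05). Hypoxia raised ISG20 in shNTC cells by 1.43 (adjusted p = 2.19e-05), and the value in shISG20 cells was 0.35 (adjusted p = 0.0806). The latter passed with a pseudocount of 0.1 (1.055), under quantile normalization (0.65), with median-of-ratios size factors (0.47), without the 50 most abundant and the mitochondrial genes (0.435), with no variance trend (0.35), by voom (1.68) and in rows that match a mouse gene alone (0.61). The difference between these hypoxia effects was -1.07 (SE 0.225, adjusted p = 0.0192), a call that was lost with a pseudocount of 0.1 (-0.66), by voom (-0.41) and without shNTC replicate 1 (-1.03) or 2 (-1.06) at 1% O2.

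HIF1A (ENSG00000100644), the oxygen-regulated subunit of HIF, stood at 112 ± 4.12 TPM in shNTC cells and 85.1 ± 4.24 TPM in shISG20 cells at 20% O2, and at 102 ± 5.90 against 71.6 ± 5.04 TPM at 1% O2 (SD, n = 3). Its RNA fell by 0.40 (limma adjusted p = 0.00384) and by 0.51 (adjusted p = 0.001) with the knockdown. The hypoxia values of HIF1A were -0.13 (adjusted p = 0.123) in shNTC and -0.25 (adjusted p = 0.00879) in shISG20 cells, and turned to 0.21 and 0.17 with median-of-ratios size factors, both called, and to 0.069 and 0.035 under quantile normalization, neither called (adjusted p = 0.386 and 0.656), so that their direction rests on the scaling. ARNT (ENSG00000143437), the partner subunit, was at 43.4 ± 0.912 TPM in shNTC and 51.3 ± 1.28 TPM in shISG20 cells at 20% O2, a log2 difference of 0.24 that missed the threshold (adjusted p = 0.0531) but passed in 6 alternatives, voom and median-of-ratios size factors among them (0.235 and 0.232). At 1% O2 it was at 53.3 ± 1.18 and 66.7 ± 6.50 TPM, higher in shISG20 cells by 0.31 (adjusted p = 0.0142), a call lost with only the groups compared (adjusted p = 0.0783) and without shNTC replicate 2 (0.30). ARNT rose with hypoxia by 0.29 (adjusted p = 0.00488) in shNTC and by 0.37 (adjusted p = 0.000918) in shISG20 cells. EPAS1 (ENSG00000116016), the other oxygen-regulated subunit, had 5 to 19 reads per group and was not tested.

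**Figure D1:**
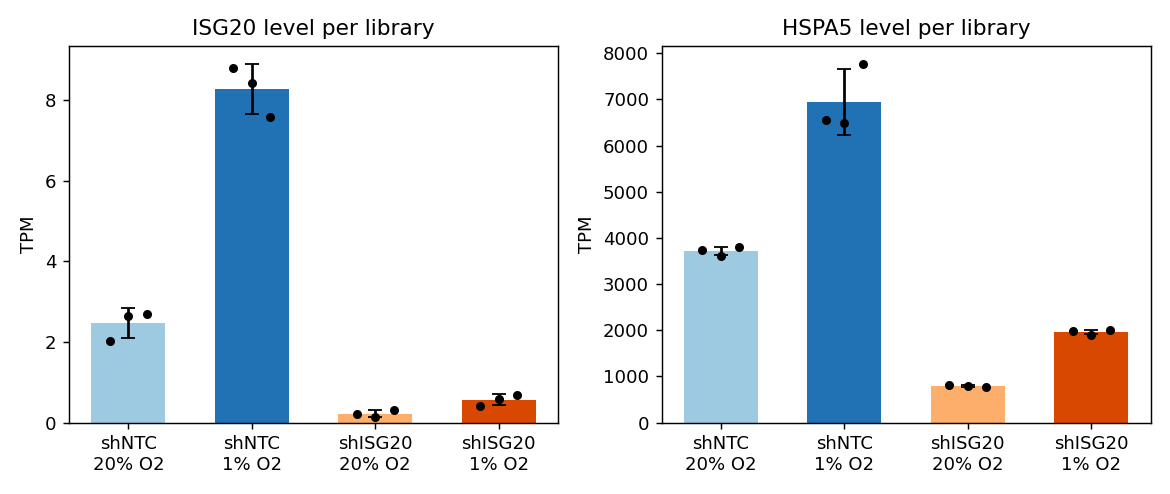
TPM of ISG20 and HSPA5 in the 4 groups, with bars at the mean, error bars of 1 SD and points for the 3 libraries. ISG20 lies at 2.46 and 8.28 TPM in shNTC cells and at 0.225 and 0.566 TPM in shISG20 cells, and HSPA5 at 3713 and 6940 TPM against 799 and 1962 TPM (20% and 1% O2 in each pair).

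At 20% O2 the smallest p in the knockdown comparison was that of HSPA5 (ENSG00000044574), a chaperone of the endoplasmic reticulum, which stood at 3713 ± 90.0 TPM in shNTC cells and 799 ± 19.6 TPM in shISG20 cells (SD, n = 3), a log2 fold change of -2.22 (SE 0.059, limma adjusted p = 1.53e-08). Among the genes that fell most were GDPD2, a glycerophosphodiester phosphodiesterase (27.2 to 3.14 TPM, -2.78, adjusted p = 6.66e-06), ANGPT1, the angiopoietin that activates TIE2 (24.5 to 4.60 TPM, -2.19), COL6A2 and COL3A1, collagen chains (-2.05 and -1.90), and NAB2, a corepressor of EGR1 (106 to 30.1 TPM, -1.80). DDAH2, of the dimethylarginine hydrolase family, fell by 1.60. NR1D1, a circadian repressor, rose from 27.5 ± 1.90 to 123 ± 12.5 TPM (2.12, SE 0.106, adjusted p = 2.51e-06), SDF2L1, a protein of the endoplasmic reticulum, from 10.2 to 37.8 TPM (1.85, adjusted p = 0.000131), and GSTA1, a glutathione transferase, from 2.38 to 9.70 TPM (1.71, adjusted p = 0.00203). BHLHE41, another circadian repressor, and DCBLD2, a membrane receptor, rose by 1.25 and 1.24. MIRLET7I, a microRNA gene, had 9 reads in shNTC cells and was listed at 0 in shISG20 cells. Its call was lost without shNTC replicate 2 (limma adjusted p = 0.0522). H2AC8, PHLDA2, EDN1, DGAT2 and ADM completed the 10 highest with 17 to 203 reads in the higher group, and each of these calls was lost in at least 1 alternative. The calls of H2AC8 and DGAT2 were lost with a pseudocount of 0.1 (3.56 and 1.72). Those of ADM, EDN1 and PHLDA2 were lost with only the groups compared (adjusted p = 0.0529, 0.0673 and 0.092), EDN1 also without shISG20 replicate 1 or 3 (1.39 each), and PHLDA2 also without shNTC replicate 1, 2 or 3 or shISG20 replicate 1 or 2 (1.04 to 1.52).

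Genes of DNA replication and S phase rose together at 20% O2. Of 26 tested members 13 rose and 0 fell by limma, 17 and 0 when adjusted over the list alone (camera adjusted p = 6.58e-11, and adjusted p = 0.0015 with an estimated correlation). At an unadjusted p under 0.05 the counts were 17 and 0, and by voom 15 and 0. PCNA, the sliding clamp of DNA polymerase, rose from 108 to 200 TPM (0.89), RRM2, a subunit of ribonucleotide reductase, from 9.42 to 21.1 TPM (1.09), and MCM5, of the replicative helicase, from 40.1 to 64.9 TPM (0.68). Of 21 mitosis genes 7 rose and 0 fell, 8 and 0 adjusted over the list alone (camera adjusted p = 9.92e-05, and adjusted p = 0.0473 with an estimated correlation). The mitosis counts were 10 and 0 at an unadjusted p under 0.05, 8 and 0 by voom, and 5 and 0 under quantile normalization or median-of-ratios size factors. TOP2A, a topoisomerase, rose from 92.4 to 129 TPM (0.48) and CCNB1, cyclin B1, from 19.9 to 30.1 TPM (0.58).

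Of 17 p53 targets 5 rose and 1 fell at 20% O2, 6 and 1 adjusted over the list alone (camera adjusted p = 0.00908, and adjusted p = 0.136 with an estimated correlation). PLK2 and CCNG1, both linked to the cell cycle, rose by 0.41 and 0.45, and BTG2, an antiproliferative gene, by 1.04. In the stress response list 4 of 24 rose and 2 fell, 11 and 3 adjusted over the list alone (camera adjusted p = 0.0179, and adjusted p = 0.0964 with an estimated correlation). Besides SDF2L1, the chaperones DNAJB9 (0.96) and HSP90B1 (0.52, 654 to 936 TPM) rose while HSPA5 fell. Of 26 nuclear genes of oxidative phosphorylation 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0292, and adjusted p = 0.0964 with an estimated correlation). COX5B (0.36) and NDUFV1 (0.30), of complexes IV and I, rose and SDHA, of complex II, fell (-1.16).

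Genes of the extracellular matrix fell in the same comparison. Of 21 members 14 fell and 1 rose, 16 and 1 adjusted over the list alone (camera adjusted p = 5.98e-11), a list call that was lost with an estimated correlation (adjusted p = 0.0964). COL1A1, a chain of type I collagen, fell from 339 ± 14.9 to 127 ± 20.4 TPM (-1.42, SE 0.123, limma adjusted p = 6.68e-05), COL12A1 from 124 to 52.7 TPM (-1.22) and FN1, fibronectin, from 1012 to 576 TPM (-0.81). LAMC1, a laminin chain named after its value was seen, was the member that rose (0.63, adjusted p = 0.000702). Of 3 tested markers of endothelial cells and fibroblasts 1 fell, COL3A1, which also stands in the matrix list (1 adjusted over the list alone, camera adjusted p = 0.0701). Of 12 markers of epithelial-mesenchymal transition 2 fell, S100A4 (229 to 94.3 TPM, -1.29) and TWIST1 (115 to 69.0 TPM, -0.72), and 1 rose. The latter was KRT19 (0.74), a call lost with only the groups compared, by voom (0.81) and without shNTC replicate 1 or 3 (0.73 and 0.72). Adjusted over the list alone 4 fell and 2 rose, and the list did not pass (camera adjusted p = 0.167).

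Glycolysis genes fell as a list at 20% O2, 6 of 20 down and 2 up, 8 and 3 adjusted over the list alone (camera adjusted p = 0.00908, and adjusted p = 0.273 with an estimated correlation). GAPDH fell from 2177 to 1446 TPM (-0.59), ALDOC, an aldolase, from 49.2 to 30.1 TPM (-0.69) and TPI1, triose phosphate isomerase, from 172 to 123 TPM (-0.48). Of 20 genes of cholesterol synthesis 3 fell and 0 rose by limma, also adjusted over the list alone (camera adjusted p = 0.0179, and adjusted p = 0.221 with an estimated correlation). The counts were 6 and 0 at an unadjusted p under 0.05, and 3 and 0 by voom. Among those called by limma were HMGCS1 (-0.69) and FDFT1 (-0.45, a call lost with only the groups compared, adjusted p = 0.0602). Of 27 other HIF targets 4 rose and 7 fell, 6 and 9 adjusted over the list alone, without a shift of the list (camera adjusted p = 0.28). DDIT4, an inhibitor of mTOR signalling, rose by 0.42, and VEGFA, the angiogenic growth factor, and PLOD2, a collagen lysyl hydroxylase, fell (-0.35 and -0.49).

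Lists of immune genes did not pass at 20% O2. Of 15 interferon-stimulated genes RSAD2, viperin, was higher, at 3.57 and 7.42 TPM (0.85, limma adjusted p = 0.0217), and adjusted over the list alone 2 were higher and 1 lower (camera adjusted p = 0.167). The RSAD2 call was lost with only the groups compared (adjusted p = 0.0613) and without shNTC replicate 1 or 3 or shISG20 replicate 2 or 3 (0.69 to 0.84). Of 11 genes of antigen presentation 2 were higher and 2 lower, 4 and 2 adjusted over the list alone (camera adjusted p = 0.167), among them PDIA3 (0.35) and PSME1 (-0.54). Of 9 chemokines and cytokines 1 was higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.581), with TGFB3 and TGFB1 down (-1.20 and -0.93). By limma 0 of 12 nucleic acid sensing genes and 0 of 6 checkpoint genes were called, also adjusted over the list alone (camera adjusted p = 0.977 and 0.368). At an unadjusted p under 0.05, 1 and 2 of them were lower, and by voom 1 sensing gene was higher, 1 lower and 0 checkpoint genes were called. The sensing list had a median of 0.03 and a mean of 0.06 but a test direction of down.

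Of 9 histone genes 1 was called at 20% O2, H2AC8, also adjusted over the list alone (camera adjusted p = 0.162). Of 25 RNA decay genes 1 was lower, DCP1A, a decapping factor (-0.70), and 0 adjusted over the list alone (camera adjusted p = 0.581). At an unadjusted p under 0.05, 1 RNA decay gene was higher and 2 lower, and by voom 2 and 1. The DCP1A call was lost when any 1 of the 6 libraries was left out (-0.59 to -0.79) and with a pseudocount of 0.1 or no filter. Ribosomal protein genes went both ways, 4 up and 7 down of 40 (4 and 10 adjusted over the list alone, camera adjusted p = 0.272), against 6 up and 4 down under quantile normalization and 3 and 5 with median-of-ratios size factors. The tested leucocyte marker CSF1R was at 1 read in each subclone (0.01, adjusted p = 0.995), and MT-CO1, of the mitochondrial genome, at 145 and 132 TPM (-0.13, adjusted p = 0.464).

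In total 727 rows rose and 943 fell at 20% O2 (limma), around a median of 0.02 over all rows. By a log2 of 1 or more 63 rose and 124 fell (187), of which 24 and 90 matched a mouse gene. Leaving out shISG20 replicate 2 lowered the 1670 calls to 1087, and leaving out replicate 3, the library labelled 484 hours, to 1144.

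**Figure D2:**
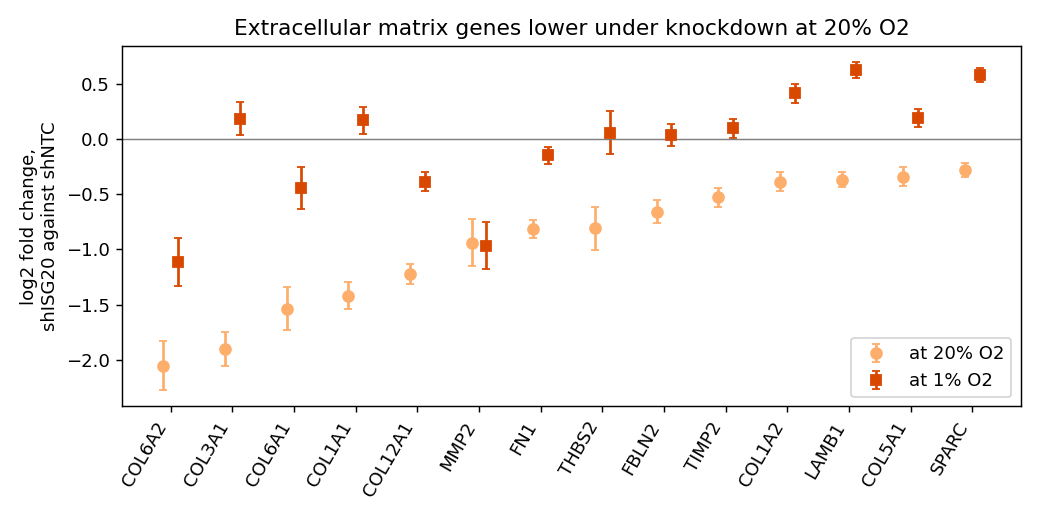
Knockdown log2 fold changes of the 14 matrix genes that fell at 20% O2, at 20% O2 and at 1% O2, with error bars of 1 SE from limma. COL1A1 lies at -1.42 at 20% O2 and 0.17 at 1% O2, and COL6A2 at -2.05 and -1.12.

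At 1% O2 HSPA5 was again among the genes that fell most with the knockdown, from 6940 ± 719 to 1962 ± 53.3 TPM (SD, n = 3; -1.82, SE 0.059, limma adjusted p = 1.24e-07). SRXN1 (sulfiredoxin) and GCLM, of glutathione synthesis, fell from 14.0 to 3.84 TPM (-1.60, adjusted p = 0.00135) and from 98.5 ± 5.92 to 38.0 ± 0.812 TPM (-1.35, adjusted p = 3.6e-06). PPP1R15A, which directs the dephosphorylation of eIF2 alpha, fell from 18.7 to 5.86 TPM (-1.53), DOLK, the dolichol kinase of protein glycosylation, from 6.19 to 1.69 TPM (-1.43), and GGT7, of the gamma-glutamyltransferase family, from 12.6 to 4.30 TPM (-1.38). CCN1, a matricellular protein, rose from 1613 ± 150 to 3344 ± 135 TPM (1.06, SE 0.064, adjusted p = 1.08e-05), GALNT3, which starts O-glycosylation, from 30.3 to 71.0 TPM (1.20, adjusted p = 6.78e-05), FST, the activin-binding follistatin, from 45.0 to 95.8 TPM (1.09), and CTPS1, a CTP synthase, from 29.4 to 59.3 TPM (0.99). NR1D1 rose from 94.2 to 187 TPM (0.99), and CFL2, an actin-binding cofilin, from 31.3 to 62.3 TPM (0.97). BCL3 and S100A15A were the highest by size (1.27 and 1.23), and EGR1 was among the lowest (-1.27). These 3 calls were lost with only the groups compared and without shNTC replicate 2 (0.99, 1.23 and -1.21). BCL3 was also lost without shISG20 replicate 1 or 3 (1.27 and 1.03), and S100A15A, with 14 and 30 reads, also without shNTC replicate 1 or 3 or shISG20 replicate 1 or 2 (0.94 to 1.38), with no filter and with no variance trend.

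Mitosis genes rose with the knockdown at 1% O2, 9 of 21 up and 0 down by limma, 12 and 0 adjusted over the list alone (camera adjusted p = 1.82e-09, and adjusted p = 0.00815 with an estimated correlation). Their counts were 14 and 0 at an unadjusted p under 0.05, and 13 and 0 by voom. TOP2A rose from 53.1 to 101 TPM (0.90), PLK1, a mitotic kinase, from 20.6 to 38.4 TPM (0.86) and CCNB1 from 15.8 to 24.1 TPM (0.57). Of 26 S phase genes 5 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0328, and adjusted p = 0.113 with an estimated correlation). RRM1 rose (0.58) and FEN1, the flap endonuclease, fell (-0.93). In the stress response list 10 of 24 fell and 2 rose, 12 and 4 adjusted over the list alone and 9 and 4 with median-of-ratios size factors (camera adjusted p = 0.00374, and adjusted p = 0.0707 with an estimated correlation). Next to HSPA5 and PPP1R15A, SLC7A5, an amino acid transporter, fell (-0.66), and ATF4, the transcription factor of the integrated stress response, fell from 300 to 235 TPM (-0.35). Of 11 antigen presentation genes 5 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00374, and adjusted p = 0.0707 with an estimated correlation). Among them PDIA3 rose by 0.45 and PSME2, of the proteasome activator, by 0.42.

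Matrix genes, which fell at 20% O2, went both ways at 1% O2, 5 up and 3 down of 21, 6 and 3 adjusted over the list alone (camera adjusted p = 0.0227, and adjusted p = 0.434 with an estimated correlation). SPARC (122 to 182 TPM, 0.58), LAMB1 (97.1 to 150 TPM, 0.63) and LAMC1 (0.58) rose, and COL6A2 fell (-1.12). Of 20 cholesterol synthesis genes 3 rose and 0 fell by limma, also adjusted over the list alone (camera adjusted p = 0.000482, and adjusted p = 0.0944 with an estimated correlation). Of the 20 genes 9 were up and 1 down at an unadjusted p under 0.05, 9 and 0 by voom, 5 and 0 with median-of-ratios size factors and 2 and 0 under quantile normalization. FDFT1, squalene synthase, rose from 12.7 to 18.4 TPM (0.51). Of 25 RNA decay genes 5 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.00864, and adjusted p = 0.275 with an estimated correlation). Their counts were 8 and 0 at an unadjusted p under 0.05 and 5 and 0 by voom, and the exonucleases ERI3 (-0.54) and XRN2 (-0.23) were among them. Of 40 ribosomal protein genes 4 rose and 0 fell, also adjusted over the list alone, against 12 and 0 with median-of-ratios size factors and 2 and 0 under quantile normalization. Their list passed (camera adjusted p = 0.000482) but not with an estimated correlation (adjusted p = 0.283), and 11 were up and 2 down at an unadjusted p under 0.05, 22 and 0 by voom.

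Lists that did not pass at 1% O2 included glycolysis, with 1 of 20 up and 7 down, 1 and 8 adjusted over the list alone (camera adjusted p = 0.0591), where PGAM1 was at 541 and 285 TPM (-0.92). Of 27 other HIF targets 2 were up and 8 down, 2 and 9 adjusted over the list alone (camera adjusted p = 0.13). NDRG1 was at 87.2 and 54.4 TPM (-0.67), ERO1A, an oxidase of the endoplasmic reticulum, at 333 and 247 TPM (-0.43) and P4HA1, a collagen prolyl hydroxylase, at 206 and 288 TPM (0.49). Transition markers had 2 up and 1 down of 12, 3 and 2 adjusted over the list alone (camera adjusted p = 0.062), with ZEB2 down (-0.56). Of 9 chemokines and cytokines 2 were up, CSF1 (0.65) and TGFB2 (0.90), and 2 down, also adjusted over the list alone (camera adjusted p = 0.364, median 0.08, mean -0.01, test direction up). Oxidative phosphorylation genes had 2 up and 3 down of 26, also adjusted over the list alone, but 3 up and 2 down with median-of-ratios size factors and 2 and 2 under quantile normalization. Their test direction was up (camera adjusted p = 0.387) with a median of -0.04 and a mean of -0.02, ATP5F1B rose by 0.33 and SDHB, of complex II, fell (-0.47).

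Of 17 p53 targets 0 were up and 2 down with the knockdown at 1% O2, also adjusted over the list alone (camera adjusted p = 0.754), 0 and 3 at an unadjusted p under 0.05 and 2 and 2 by voom. Of 12 sensing genes 1 was down, ADAR, an RNA editing enzyme (-0.78, a call lost with only the groups compared, adjusted p = 0.0774), also adjusted over the list alone (camera adjusted p = 0.754). By limma 0 of 15 interferon-stimulated genes, 0 of 6 checkpoint genes, 0 of 9 histone genes and 0 of 3 endothelial and fibroblast markers were called, also adjusted over the list alone (camera adjusted p = 0.82, 0.158, 0.364 and 0.963). At an unadjusted p under 0.05, 1 interferon-stimulated gene was up and 1 down, 1 checkpoint gene up, 1 histone gene down and 0 markers, and by voom 1 checkpoint gene was called and 0 of the other 3 lists. The interferon list, with a median and a mean of -0.04, and the markers, with a median of -0.22 and a mean of -0.10, had a test direction of up. CSF1R was at 2.56 and 1.84 TPM (-0.34, limma adjusted p = 0.426) and MT-CO1 at 159 and 149 TPM (-0.10, adjusted p = 0.555).

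The knockdown comparison at 1% O2 called 2001 rows with limma, 611 up and 1390 down, around a median of -0.07. By a log2 of 1 or more 41 rose and 106 fell (147), of which 11 and 60 matched a mouse gene. With median-of-ratios size factors 1016 of 2103 calls were up (48.3%). The number fell to 957 with only the groups compared, to 1155 without shNTC replicate 2 and to 1319 without shISG20 replicate 3.

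Of the rows called for the knockdown at both oxygen levels, comparisons that share no library, 460 of 568 (81.0%) moved in the same direction. Both up were 147 rows against 30.9 for independent lists and both down 313 against 91.1, while 72 and 36 rows moved in opposite directions against 70.2 and 40.0. Among those that moved alike were HSPA5 and COL6A2 (down) and NR1D1 and TOP2A (up). Across all tested rows, which are not independent replicates, the log2 fold changes correlated at r = 0.155 (Spearman's rho 0.163).

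Hypoxia in shNTC cells raised genes of glycolysis and other HIF targets. SLC2A1, the glucose transporter GLUT1, rose from 46.3 ± 3.70 to 686 ± 24.7 TPM (SD, n = 3; 3.86, SE 0.078, limma adjusted p = 5.89e-11), BNIP3, a mitophagy receptor, from 5.24 to 117 TPM (4.25), ENO2, an enolase, from 37.0 to 508 TPM (3.76), EGLN3, a HIF prolyl hydroxylase, from 2.00 to 39.0 TPM (3.75), and ADM, adrenomedullin, from 1.81 to 37.9 TPM. NDRG2 and NOS2, the inducible nitric oxide synthase, rose by 4.55 and 4.39 from 12 reads and 1 read at 20% O2, and KRT19, a keratin, by 3.81. EGR1, an immediate early transcription factor, fell from 249 ± 31.2 to 9.78 ± 3.13 TPM (-4.57, adjusted p = 1.97e-07), OGN, osteoglycin, from 153 to 5.58 TPM (-4.55), SLC24A3, an ion exchanger, from 86.2 to 3.23 TPM (-4.37), PTX3, a pentraxin, from 496 to 33.0 TPM (-3.87), and CSF1, the macrophage growth factor, from 207 to 24.2 TPM (-3.05).

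Of 20 glycolysis genes 19 rose and 0 fell in shNTC cells at 1% O2, and of 27 other HIF targets 26 rose and 0 fell, also adjusted over the list alone. The limma counts were the same at an unadjusted p under 0.05, and by voom 19 and 27 rose and 0 fell. The medians were 1.96 and 2.00 (camera adjusted p = 2.01e-26 and 2.24e-27, and adjusted p = 0.00431 and 0.000147 with an estimated correlation). GAPDH rose from 2177 to 11860 TPM (2.44), PGK1, a glycolytic kinase, from 972 to 4158 TPM (2.09), ERO1A from 31.0 to 333 TPM (3.38) and BNIP3L, a mitophagy receptor, from 93.8 to 378 TPM (2.00). Genes of cholesterol synthesis rose as well, 19 of 20 up and 0 down, also adjusted over the list alone, at an unadjusted p under 0.05 and by voom (median 1.17, camera adjusted p = 1.49e-13, and adjusted p = 0.00431 with an estimated correlation). FDPS rose from 25.7 to 112 TPM (2.08) and HMGCS1 by 1.66. Transition markers had 7 up and 3 down of 12, also adjusted over the list alone (camera adjusted p = 0.0103, and adjusted p = 0.152 with an estimated correlation). VIM, vimentin, rose from 1979 to 6851 TPM (1.79) together with the epithelial keratin KRT8 (1.77), while ZEB2, a mesenchymal transcription factor, fell (-1.29).

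Genes of S phase and RNA decay fell in shNTC cells at 1% O2. Of 26 S phase genes 16 fell and 0 rose by limma, also adjusted over the list alone and at an unadjusted p under 0.05, and 15 fell and 4 rose by voom, 15 and 3 with median-of-ratios size factors and 15 and 2 under quantile normalization (camera adjusted p = 0.0194, and adjusted p = 0.0888 with an estimated correlation). PRIM1, a primase subunit, fell from 13.7 to 1.18 TPM (-2.75) and POLA1, of DNA polymerase alpha, from 26.4 to 5.41 TPM (-2.09). Of 25 RNA decay genes 19 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.0103, and adjusted p = 0.27 with an estimated correlation). Their counts were 19 down and 1 up at an unadjusted p under 0.05, 12 and 1 by voom, 8 and 1 with median-of-ratios size factors and 9 and 1 under quantile normalization. DIS3, an exosome nuclease, fell from 34.1 to 6.44 TPM (-2.26).

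Other lists did not pass in shNTC cells. Interferon-stimulated genes had 1 up and 10 down of 15 (camera adjusted p = 0.27), with IFIH1, the RNA sensor MDA5, at -1.77. Nucleic acid sensing genes had 1 up and 8 down of 12 (camera adjusted p = 0.182), with NFKB1 at -1.54 and RELA at -0.81. Stress response genes had 8 up and 16 down of 24 (camera adjusted p = 0.574). HSPA5 (0.90, named after its value was seen), HSP90B1 (1.39) and PDIA4 (1.67) rose, and the transcription factor ATF5 (-2.98) and CHAC1 (-1.90) fell. Matrix genes had 4 up and 13 down of 21 (4 and 15 adjusted over the list alone, camera adjusted p = 0.27), with FN1 from 1012 to 367 TPM (-1.47). Mitosis genes had 0 up and 12 down of 21 by limma and at an unadjusted p under 0.05, 1 and 9 by voom, 1 and 8 with median-of-ratios size factors and 2 and 8 under quantile normalization (camera adjusted p = 0.202, CDC20 -1.13). Antigen presentation genes had 3 up and 5 down of 11 (camera adjusted p = 0.741), with CALR at 0.77 and PSME2 at -0.98, and 4 and 4 with median-of-ratios size factors or quantile normalization. Chemokines and cytokines had 2 up and 3 down of 9 (camera adjusted p = 0.953). Checkpoint genes had 1 up and 3 down of 6 (camera adjusted p = 0.611), with NT5E, which makes adenosine, at -1.30, and 2 and 2 with median-of-ratios size factors but 1 and 3 under quantile normalization. Where no other count is given, the counts were the same when adjusted over the list alone.

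Ribosomal protein genes had 5 up and 23 down of 40 in shNTC cells (camera adjusted p = 0.182) and 6 and 22 under quantile normalization, but 23 up and 3 down with median-of-ratios size factors. Oxidative phosphorylation genes had 3 up and 8 down of 26, 2 and 8 adjusted over the list alone (camera adjusted p = 0.764), but 8 up and 2 down with these factors and 6 and 3 under quantile normalization. Targets of p53 had 0 up and 7 down of 17 by limma and at an unadjusted p under 0.05, with PLK2 at -0.85 (camera adjusted p = 0.574), but 2 up and 2 down with these factors, 2 and 4 under quantile normalization and 3 and 2 by voom. Of 9 histone genes 1 was up, H2AC8 (1.20), and 0 adjusted over the list alone or by voom, against 1 at an unadjusted p under 0.05 (camera adjusted p = 0.574). The H2AC8 call was also lost with a pseudocount of 0.1, with no filter, and without shNTC replicate 1 or 2 at 20% O2 or 1 or 3 at 1% O2 (0.78 to 1.39). The lists of antigen presentation, chemokines, oxidative phosphorylation and histones had a median and mean below 0 and a test direction of up. Of the fibroblast markers COL3A1 (-2.79) and PDGFRB (-2.04) fell and PDGFRA rose (0.90, from 19 to 96 reads), 1 up and 2 down of 3 (camera adjusted p = 0.574). The leucocyte marker CSF1R rose from 1 to 72 reads (1.75, limma adjusted p = 0.000139), and MT-CO1 was at 145 and 159 TPM (0.15, adjusted p = 0.247), a difference that passed with median-of-ratios size factors (0.49) and quantile normalization (0.31).

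In shNTC cells limma called 7326 rows for hypoxia, 1847 up and 5479 down, 2541 of them by a log2 of 1 or more. The median over all rows was -0.28 and moved to 0 with median-of-ratios size factors, which gave 3311 up of 6521 calls (50.8%), and quantile normalization gave 2913 up of 6499 (44.8%). Relative to that median the glycolysis list stood at 2.24, the other HIF targets at 2.28, cholesterol synthesis at 1.45, S phase at -0.67 and RNA decay at -0.29.

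**Figure D3:**
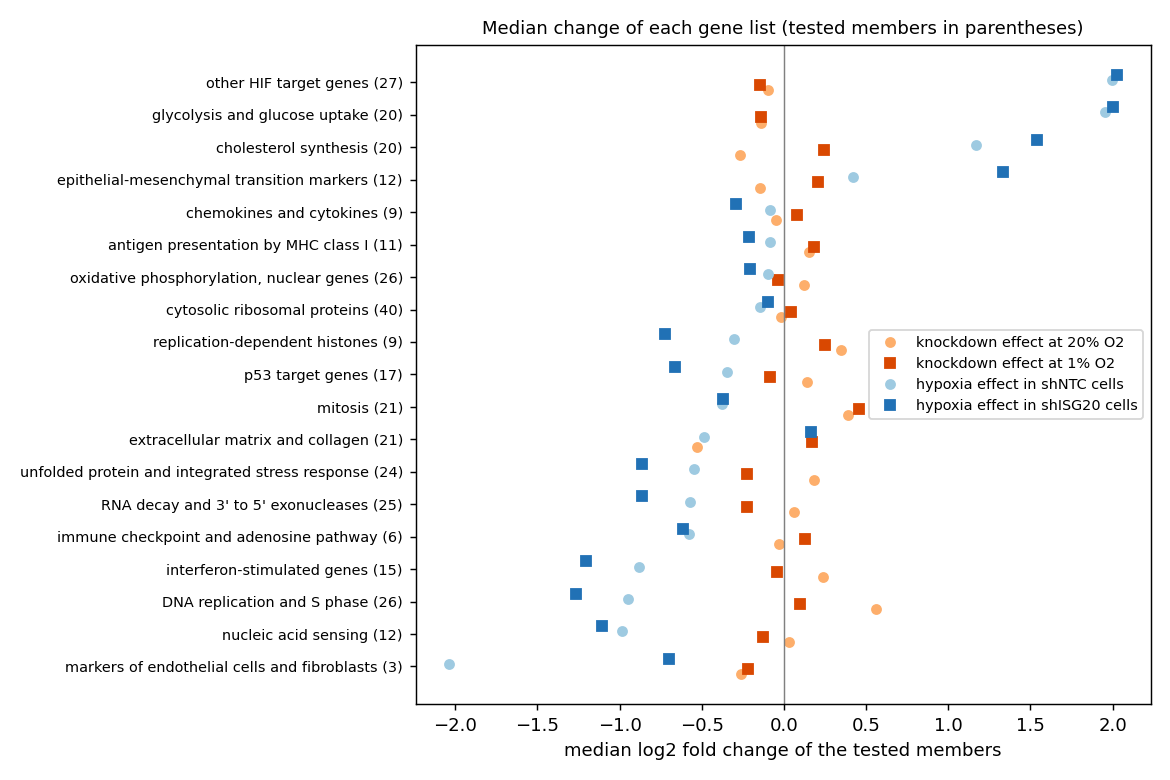
Median log2 fold change of each gene list (tested members in parentheses) in the 4 comparisons between groups, as points on the log2(TPM + 1) scale. Glycolysis, the other HIF targets and cholesterol synthesis lie at 1.96, 2.00 and 1.17 for hypoxia in shNTC cells, S phase genes at 0.56 for the knockdown at 20% O2, and ribosomal proteins at -0.15 for hypoxia in shNTC cells, a value that turns to 0.19 with median-of-ratios size factors and stays below 0 under quantile normalization (-0.21).

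In shISG20 cells hypoxia raised SLC2A1 from 43.5 ± 4.33 to 524 ± 20.7 TPM (SD, n = 3; 3.56, SE 0.078, limma adjusted p = 6.64e-11), BNIP3 from 4.84 to 94.7 TPM (4.05), ENO2 from 25.9 to 351 TPM (3.71), ALDOC from 30.1 to 365 TPM (3.56) and EGLN3 from 1.18 to 22.4 TPM (3.43). MGARP, a mitochondrial protein, was listed at 0 in all libraries at 20% O2 and at 12.3 ± 1.81 TPM at 1% O2. NOP56 and NOP58, core proteins of box C/D small nucleolar ribonucleoproteins, fell from 431 ± 15.7 to 28.3 ± 1.09 TPM (-3.88, adjusted p = 2.11e-11) and from 666 to 62.4 TPM (-3.40). RRP12, of ribosome export, fell from 46.9 to 2.47 TPM (-3.79), DGCR8, of microRNA processing, from 44.2 to 2.82 TPM (-3.58), SLC24A3 from 64.8 to 1.13 TPM (-4.95) and EGR1 from 83.9 to 3.61 TPM (-4.28). MIR708 had 7 reads at 20% O2 and was listed at 0 at 1% O2.

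In shISG20 cells 19 of 20 glycolysis genes, 26 of 27 other HIF targets and 19 of 20 cholesterol synthesis genes rose and 0 fell, also adjusted over the list alone. The limma counts were the same at an unadjusted p under 0.05, and by voom 20, 27 and 20 rose and 0 fell. The camera adjusted p-values were 6.81e-24, 3.94e-24 and 1.5e-15, and 0.00599, 0.000238 and 0.00301 with an estimated correlation. GAPDH rose by 2.69, PGK1 by 2.18, ERO1A by 2.77, HMGCS1 by 2.70 and FDPS by 2.29. S phase genes fell, 21 of 26 down and 1 up, also adjusted over the list alone, and 18 and 3 under quantile normalization (camera adjusted p = 0.000475, and adjusted p = 0.016 with an estimated correlation). PRIM1 fell from 22.8 to 1.33 TPM (-3.35) and MCM5 from 64.9 to 18.2 TPM (-1.78). RNA decay genes had 19 down and 1 up of 25, also adjusted over the list alone (camera adjusted p = 0.000777, and adjusted p = 0.14 with an estimated correlation). DIS3 stood at -2.59 and EXOSC2, an exosome subunit, at -2.77. Transition markers had 8 up and 3 down of 12, also adjusted over the list alone (camera adjusted p = 0.000475, and adjusted p = 0.0508 with an estimated correlation), with VIM at 2.14 and ZEB2 at -1.80. Matrix genes had 9 up and 4 down of 21, also adjusted over the list alone (camera adjusted p = 0.0038, and adjusted p = 0.406 with an estimated correlation). Their counts were 13 and 3 with median-of-ratios size factors and 11 and 2 under quantile normalization. COL1A1 rose from 127 to 311 TPM (1.29) and FBLN2, fibulin 2, from 20.3 to 64.4 TPM (1.62), and MMP2, a matrix metalloproteinase, fell (-2.30).

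The remaining lists did not pass in shISG20 cells. Stress response genes had 6 up and 17 down of 24 (camera adjusted p = 0.0955), with ATF4 at -1.57, ATF5 at -3.03, SLC7A5 at -2.29 and HSPA5, named after its value was seen, at 1.30. Interferon-stimulated genes had 1 up and 13 down of 15 (1 and 14 adjusted over the list alone, camera adjusted p = 0.0931), and 1 and 8 under quantile normalization, with IFIH1 at -2.39. Sensing genes had 1 up and 9 down of 12 (camera adjusted p = 0.157), with ADAR at -1.71. Targets of p53 had 0 up and 11 down of 17 by limma and at an unadjusted p under 0.05, 1 and 8 by voom, and 1 and 7 with median-of-ratios size factors or quantile normalization (camera adjusted p = 0.128, PLK2 -1.35). Chemokines and cytokines had 3 up and 4 down of 9 (camera adjusted p = 0.826), with TGFB1 at 1.69 and CSF1 at -2.56. Of 9 histone genes 1 was down (camera adjusted p = 0.881). Of the fibroblast markers PDGFRB fell (-2.03) and PDGFRA rose (0.67), 1 up and 2 down of 3 (camera adjusted p = 0.881). CSF1R rose from 1 to 44 reads (1.40, limma adjusted p = 0.000541), and MT-CO1 was at 132 and 149 TPM (0.17, adjusted p = 0.16), a difference that passed with median-of-ratios size factors (0.59) and quantile normalization (0.36).

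Ribosomal proteins had 4 up and 19 down of 40 in shISG20 cells (camera adjusted p = 0.881) and 8 and 24 under quantile normalization, against 32 up and 0 down with median-of-ratios size factors. Mitosis genes had 0 up and 11 down of 21 by limma (camera adjusted p = 0.805), 0 and 12 at an unadjusted p under 0.05 and 7 and 4 by voom, against 6 and 3 with these factors and 4 and 3 under quantile normalization. Oxidative phosphorylation genes had 1 up and 9 down of 26 (1 and 8 adjusted over the list alone, camera adjusted p = 0.881) against 6 and 2 with these factors and 6 and 8 under quantile normalization. Antigen presentation genes had 4 up and 5 down of 11 (camera adjusted p = 0.622) against 4 and 3 with these factors and 4 and 4 under quantile normalization. Checkpoint genes had 2 up and 4 down of 6 (camera adjusted p = 0.881) against 2 and 1 with these factors and 1 and 1 under quantile normalization. The lists of antigen presentation, chemokines, checkpoint genes and histones had a median and mean below 0 and a test direction of up. Where no other count is given, those of the lists in shISG20 cells were the same when adjusted over the list alone.

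For hypoxia in shISG20 cells limma called 8173 rows, 2021 up and 6152 down, 3498 of them by a log2 of 1 or more, around a median of -0.35. With median-of-ratios size factors 3781 of 7609 were up (49.7%) and under quantile normalization 3338 of 7288 (45.8%). Of the 6207 rows called in both subclones, comparisons that share no library, 6137 (98.9%) moved in the same direction: 1435 up in both, against 259.4 for independent lists, and 4702 down in both, against 2342.5. Opposite directions were taken by 35 and 35 rows. Under quantile normalization 2336 rows were up in both (675.8 for independent lists) and 2872 down in both (984.4). The log2 fold changes correlated across rows at r = 0.786 (rho 0.758), and SLC2A1, BNIP3, EGR1 and SLC24A3 moved alike.

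The interaction, the hypoxia effect in shISG20 cells minus that in shNTC cells, was positive for matrix genes such as COL1A1, COL3A1, LAMB1 and SPARC. COL1A1 was at 339 and 277 TPM in shNTC cells at 20% and 1% O2 and at 127 and 311 TPM in shISG20 cells, an interaction of 1.59 (SE 0.175, limma adjusted p = 0.00105), and COL3A1 had 2.09 (SE 0.215, adjusted p = 0.001), LAMB1 0.99 and SPARC 0.86. Of 21 matrix genes 12 had a positive and 0 a negative interaction (limma; 15 and 0 at an unadjusted p under 0.05, 14 and 0 by voom), and 15 and 0 when adjusted over the list alone (camera adjusted p = 1.12e-14; adjusted p = 0.055 with an estimated correlation). PMM1, a phosphomannomutase, was at 17.3 and 40.7 TPM in shNTC cells and at 32.9 and 20.7 TPM in shISG20 cells (-1.83, adjusted p = 7.69e-05). HMOX1, heme oxygenase 1, went from 21.2 to 69.2 TPM in shNTC cells and from 31.8 to 33.5 TPM in shISG20 cells (-1.59, adjusted p = 0.000425), and DNAJC11 from 26.3 to 10.8 and from 36.2 to 4.55 TPM (-1.52). HSPA5, named here after its value was seen, had an interaction of 0.40 (SE 0.083, adjusted p = 0.0187).

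Stress response genes had 1 positive and 9 negative interactions of 24, 1 and 15 adjusted over the list alone (camera adjusted p = 1.45e-05, and adjusted p = 0.027 with an estimated correlation). PPP1R15A stood at -1.51, DNAJB9 at -1.13 and ATF4 at -0.60. S phase genes had 0 positive and 4 negative of 26, 1 and 10 adjusted over the list alone (camera adjusted p = 0.000304, likewise 0.027). Their counts were 1 and 11 at an unadjusted p under 0.05 and 1 and 6 by voom, with PCNA at -0.95 and FEN1 at -1.21. Cholesterol synthesis had 3 positive and 0 negative of 20, 7 and 0 adjusted over the list alone (camera adjusted p = 5.34e-06, likewise 0.04). The counts were 10 and 0 at an unadjusted p under 0.05, 7 and 0 by voom, 6 and 0 with median-of-ratios size factors and 5 and 0 under quantile normalization, with HMGCS1 at 1.04 and FDFT1 at 0.95.

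The interaction calls of 5 more lists were lost with an estimated correlation (adjusted p given second). Ribosomal proteins had 5 positive and 0 negative of 40, 8 and 1 adjusted over the list alone (camera adjusted p = 0.000304 and 0.236). They had 2 and 1 under quantile normalization and 6 and 0 with median-of-ratios size factors. By limma 12 and 2 passed at an unadjusted p under 0.05, and 16 and 0 by voom. RNA decay genes had 0 and 3 of 25, 0 and 4 adjusted over the list alone (camera adjusted p = 0.00553 and 0.16). They had 0 and 7 at an unadjusted p under 0.05 and 0 and 4 by voom. Targets of p53 had 1 and 4 of 17, 1 and 8 adjusted over the list alone (camera adjusted p = 0.00955 and 0.137). They had 1 and 2 with median-of-ratios size factors or quantile normalization. Transition markers had 3 and 0 of 12, 3 and 1 adjusted over the list alone (camera adjusted p = 0.0114 and 0.137). They had 6 and 1 at an unadjusted p under 0.05 and 3 and 2 by voom. Mitosis genes had 1 and 0 of 21, also adjusted over the list alone (camera adjusted p = 0.0412 and 0.16). They had 5 and 1 at an unadjusted p under 0.05 and 4 and 0 by voom.

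Lists without a called interaction included glycolysis, with 3 positive and 4 negative of 20 (camera adjusted p = 0.388, median 0.09, mean -0.04, test direction up), 4 and 3 with median-of-ratios size factors and 3 and 4 under quantile normalization. ALDOC stood at 0.72 and PGAM1 at -0.52. The other HIF targets had 2 and 5 of 27 (camera adjusted p = 0.713), with P4HA1 at 0.84, NDRG1 at -1.07 and DDIT4 at -0.72. Oxidative phosphorylation had 2 and 4 of 26 (camera adjusted p = 0.65), with SDHB at -0.56, 2 and 1 with median-of-ratios size factors and 1 and 3 under quantile normalization. Antigen presentation had 1 positive of 11 (camera adjusted p = 0.0535). Chemokines and cytokines had 2 positive of 9 (camera adjusted p = 0.0979, median -0.07, mean 0.18, test direction up), with TGFB1 at 1.08. Histones had 1 negative of 9 (camera adjusted p = 0.713) and the fibroblast markers 1 positive of 3, COL3A1 (camera adjusted p = 0.108). These counts were the same when adjusted over the list alone. By limma 0 interferon-stimulated, 0 sensing and 0 checkpoint genes were called (camera adjusted p = 0.411, 0.713 and 0.0746). At an unadjusted p under 0.05 they had 3 negative, 1 negative and 2 positive members, by voom 1 negative, 1 negative and 2 positive, and adjusted over the list alone 0, 0 and 1. With median-of-ratios size factors 2 checkpoint genes were positive, and 1 under quantile normalization. CSF1R had -0.34 (limma adjusted p = 0.625) and MT-CO1 0.03 (adjusted p = 0.935).

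In total 997 rows had an interaction past the threshold, 377 positive and 620 negative, and 187 of a log2 of 1 or more. Of the positive ones 108 were up and 193 down with hypoxia in shNTC cells, and of the negative ones 133 were up and 368 down. Positive calls were 590 of 1046 (56.4%) with median-of-ratios size factors and 473 of 956 (49.5%) under quantile normalization. The number was 1788 by voom, and it fell to 655 without shNTC replicate 1 at 20% O2, 635 without shNTC replicate 2 at 1% O2, and 595 and 632 without shISG20 replicate 2 and 3 at 20% O2.

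The hypoxia effect in shNTC cells and the knockdown effect at 1% O2 share the shNTC libraries at 1% O2. Among rows called in both, 121 were up in both (78.4 for independent lists), 803 down in both (529.3), 236 up with hypoxia and down with the knockdown (178.4) and 320 the reverse (232.7). Under quantile normalization these numbers were 190 (139.1), 471 (264.2), 289 (214.6) and 288 (171.2). SLC2A1 (3.86 and -0.39), GCLM (0.92 and -1.35) and HMOX1 (1.66 and -1.03), named after their values were seen, were up with hypoxia and down with the knockdown. In 100 simulations of unchanged groups against the shared libraries a median of 0 and at most 1 row was called in both. The correlation across rows was -0.074 against a simulated -0.501 (-0.53 to -0.456), and the covariance -0.0239 against -0.0447. No simulated value gives a baseline where rows change, and the shared libraries were too few to split. Part of the excess in opposite directions may come from sharing.

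A pseudogene row often moved as the gene it is named after. Over 3446 such rows and 1044 genes the log2 fold changes correlated across rows at r = 0.340 and 0.350 for the knockdown at 20% and 1% O2, 0.796 and 0.823 for hypoxia in shNTC and shISG20 cells, and 0.293 for the interaction. For hypoxia in shNTC cells 1074 rows were called together with the gene, 1069 of them in its direction.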

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

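Results are listed here where the response to 1% O2 differed between shISG20 and shNTC cells by the test of the interaction, and 3 patterns are weighed. The tests that set hairpin, subclone, stress response, cell mixture, abundant genes, pseudogene names and total RNA against a pattern, and the splits of the libraries, were chosen after the results were seen. The interaction was called for 997 rows (limma). Of 100 splits of residuals of a fit with knockdown and oxygen alone, 1, the real one, reached 997. The highest other called 6 (186 with values split), which argues against a chance split of these libraries. For the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05: the real split, 1 of the 10, called 1670, 2001, 7326 and 8173 rows, and the highest of the others 8, 3, 4 and 1 (knockdown at 20% and 1% O2, hypoxia in shNTC and shISG20 cells).

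Among the highest interactions were COL3A1 (2.09), ADAMTSL4 (1.78), CIB2 (1.63), COL1A1 (1.59), NAB2 (1.52), VDR, the vitamin D receptor (1.51), and LURAP1L (1.49). GDPD2 (2.22) and ANGPT1 (1.74) were lost with a pseudocount of 0.1 (0.58 and 0.79) and by voom (0.97 and 0.38), and GDPD2 was listed at 0 in shISG20 cells at 1% O2. MIRLET7I (5.38) was listed at 0 in shISG20 cells at 20% O2, so that its fitted value depends on the pseudocount, and was lost with a pseudocount of 3 (3.54), with no filter, with no variance trend and without 8 of the 12 single libraries, namely shNTC replicate 1 or 2 at 20% O2 and each shISG20 library (4.74 to 5.66). Among the lowest were PMM1 (-1.83), SRXN1 (-1.74), SDF2L1 (-1.61), HMOX1 (-1.59), GNPDA1 (-1.53), DNAJC11 (-1.52) and PHLDA2 (-2.52). H2AC8 (-3.21) and DGAT2 (-1.56) were lost with a pseudocount of 0.1 (-5.71 and -2.70), and GSTA2 (-1.51) with pseudocounts of 0.1 and 3 (-2.96 and -0.815), with no filter, under quantile normalization or median-of-ratios size factors (-1.33 each), with no variance trend and with quality weights (-1.42). GSTA2 was also lost without any 1 of 10 libraries, all but shNTC replicate 2 and shISG20 replicate 2 at 20% O2 (-1.61 to -1.22). ISG20 itself stood at -1.07, lost in the settings given for it in Results.

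In the list of matrix genes (camera adjusted p = 1.12e-14, and adjusted p = 0.055 with an estimated correlation, where the call was lost) LAMB1 stood at 0.99 and SPARC at 0.86. The calls of the next 3 lists were kept with an estimated correlation (adjusted p given second). In the stress response list (adjusted p = 1.45e-05 and 0.027) PPP1R15A stood at -1.51, DNAJB9 at -1.13 and ATF4 at -0.60. In cholesterol synthesis (adjusted p = 5.34e-06 and 0.04) HMGCS1 stood at 1.04 and FDFT1 at 0.95. In S phase (adjusted p = 0.000304 and 0.027) FEN1 stood at -1.21, PCNA at -0.95, MCM3 at -0.93 and MCM5 at -0.82. The calls of another 5 lists were lost with it. Ribosomal proteins (adjusted p = 0.000304, and adjusted p = 0.236 with an estimated correlation) held RPL37 (0.30), RPL15 (0.29) and RPS12 (0.11), each lost with no variance trend (adjusted p = 0.0814, 0.0707 and 0.455). RNA decay genes (adjusted p = 0.00553, and adjusted p = 0.16 with an estimated correlation) held AEN (-0.65), ERI3 (-0.41) and XRN2 (-0.18). Of p53 targets (adjusted p = 0.00955, and adjusted p = 0.137 with an estimated correlation) SESN1 stood at 0.97, AEN at -0.65, PHLDA3 at -0.51, PLK2 at -0.50 and BAX at -0.39. Of transition markers (adjusted p = 0.0114, and adjusted p = 0.137 with an estimated correlation) TWIST1 stood at 1.02, S100A4 at 0.91 and VIM at 0.35 (0.18 under quantile normalization, where the call was lost), and of mitosis genes (adjusted p = 0.0412, and adjusted p = 0.16 with an estimated correlation) PLK1 at 0.59.

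In lists without a called interaction members past the threshold were ALDOC (0.72), GAPDH (0.25, lost with no variance trend, adjusted p = 0.12), PGAM1 (-0.52) and SLC16A3 (-0.76, lost without shNTC replicate 2 at 1% O2, -0.71) in glycolysis, and P4HA1 (0.84), NDRG1 (-1.07), DDIT4 (-0.72) and ERO1A (-0.61) among other HIF targets. Others were TGFB1 (1.08) and CSF1 (0.48) among cytokines, PSME1 (0.41) in antigen presentation, and SDHB (-0.56), COX5B (-0.40) and ATP5F1B (0.15) in oxidative phosphorylation, where ATP5F1B was lost with no variance trend (adjusted p = 0.31). COX5B was lost without shNTC replicate 1 (-0.38) or 3 (-0.37) at 20% O2 and with median-of-ratios size factors (-0.32), voom (-0.31) or no variance trend. Quantile normalization also ended the calls of RPS12 (0), ATP5F1B (0.11), AEN (-0.55) and PHLDA3 (-0.46), and median-of-ratios size factors those of XRN2 (-0.10, as by voom), BAX (-0.31) and PHLDA3 (-0.425).

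Calls of 10 of these genes were lost without most single libraries, with values close to those with all 12. They are PSME1 (0.34 to 0.44; past the threshold only without replicate 1 of shNTC at 1% O2 or of shISG20 at either level), CSF1 (0.43 to 0.49; past it only without shNTC replicate 1 at 20% O2 or 2 at 1% O2, or shISG20 replicate 3 at 20% O2 or 1 at 1% O2) and PLK1 (0.50 to 0.61; only without shNTC replicate 2 at 20% O2 or shISG20 replicate 3 at 1% O2). ERI3 (-0.43 to -0.36) and XRN2 (-0.19 to -0.17) were past it only without shNTC replicate 3 or shISG20 replicate 2 at 1% O2, AEN (-0.68 to -0.55) only without shISG20 replicate 1 at 20% O2 or 3 at 1% O2, and RPS12 (0.10 to 0.12) only without shNTC replicate 1 at 20% O2. BAX (-0.41 to -0.35) was past it only without shNTC replicate 3 at 20% O2 or 1 at 1% O2, or shISG20 replicate 1 at 20% O2 or 3 at 1% O2. PHLDA3 (-0.50 to -0.44) was past it only without replicate 2 of shNTC or 1 of shISG20 at either level, and SESN1 (0.84 to 0.99) only without shNTC replicate 3 or shISG20 replicate 2 at 1% O2 or shISG20 replicate 3 at 20% O2.

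HSPA5 fell in shISG20 cells by 2.22 on the log2 scale at 20% O2. If reads had moved to related HSP70 rows, the 35 rows with an HSPA name together would have kept their number, but they fell by 107% of the fall of HSPA5 in reads relative to depth, which argues against it. A fall of the stress response genes as a set is argued against by the other 23 members, with a median of 0.19 (quartiles 0.004 and 0.253; 6 below 0, the lowest SLC7A11 at -0.47). A second effect of the hairpin, or a trait of the subclone, predicts a fall at 1% O2 as well, and HSPA5 was at -1.82 there. An effect of ISG20 loss predicts the same, so these cannot be told apart where the labels mark no other hairpin or subclone.

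Matrix genes fell in shISG20 cells at 20% O2, 14 of 21 by limma. A single library as the source is argued against by the leave-one-out fits, with 9 lower at the least (without shNTC replicate 1 or without shISG20 replicate 2), and the scaling by quantile and median-of-ratios fits, with 14 lower at the least. A smaller and constant share of fibroblast-like cells in the shISG20 culture would lower the 14 genes at 1% O2 too, where their median was 0.079 (quartiles -0.325 and 0.189; 5 below 0) against -0.81 at 20% O2, while COL6A2 (-1.12), MMP2 (-0.97) and COL12A1 (-0.39) were lower there as well. A share that changes with oxygen was not tested. An effect of ISG20 loss at 20% O2 and a trait of the subclone both stay open, the former as a hypothesis.

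Most rows called for hypoxia in shNTC cells were lower at 1% O2, around a median of -0.28. A few abundant genes taking the reads are argued against as the whole source by the median of -0.22 without the 50 most abundant and the mitochondrial genes, and pseudogene rows by the median of -0.33 in rows that match a mouse gene. The 1847 rows that rose held 37.8% of TPM at 1% O2 and 20.0% at 20% O2, a gain that lowers the TPM of the other rows by construction. Whether the other transcripts also fell per cell cannot be told, because TPM holds no total per cell, and median-of-ratios size factors set the median to 0. The design names hypoxia as the biological difference, and its effect on total RNA was not tested.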

How the results depend on the processing

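Voom and the fit of mouse-matched rows were added after the data were seen. Of 418 named gene results 387 were called, and 44 of these were lost when some single library was left out. Rows called kept within 1.5 times of the numbers above, except as follows. A log2 fold change of at least 1 left 187, 147, 2541, 3498 and 187 rows (knockdown at 20% and 1% O2, hypoxia in shNTC and shISG20 cells, interaction) and 14, 1963 and 25 rows called in the same direction in both comparisons of each overlap, by construction. At that size 386, 418 and 49 rows up and 1371, 1988 and 74 down matched a mouse gene for hypoxia (shNTC, shISG20) and the interaction. Fitting only the groups compared gave 957 for the knockdown at 1% O2 but 1410 at 20% O2, and voom gave 1788 for the interaction. Neither cause was tested. Leaving out 1 library gave 1087 (without shISG20 replicate 2) to 1160 for the knockdown at 20% O2. At 1% O2 it gave 1155 (without shNTC replicate 2) to 1889. For hypoxia it gave 6617 to 6730 and 7590 to 7779. The interaction had 595 (without shISG20 replicate 2 at 20% O2) to 1043, above the full 997. Without the library labelled 484 hours the numbers were 1144, 7637 and 632.

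Camera called 38 of 95 list tests, 13 with an estimated correlation and 71 with fry, which asks another question. Fry gave the opposite direction for interferon-stimulated genes (adjusted p = 0.463), endothelial and fibroblast markers (0.531) and oxidative phosphorylation (0.465) in the knockdown at 1% O2, for antigen presentation (0.000314), chemokines (2.13e-05), oxidative phosphorylation (5.99e-05) and histones (0.245) in shNTC hypoxia, and for antigen presentation (0.0467), chemokines (0.000381), checkpoint genes (0.00884) and histones (0.00793) in shISG20 hypoxia.

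Replicate numbers did not pair the samples: same-numbered deviations correlated at -0.042 to 0.015, and in 5 of 36 comparisons a library correlated best with its own number. With the replicate number as a block the numbers of calls were 1438, 1748, 7129, 8087 and 726, and the list calls 38. The sensing list at 20% O2 turned direction under the block without a call (adjusted p = 0.984).

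Some genes turned direction with the scaling, and the cause was not tested beyond the shift of all rows. For hypoxia in shNTC cells these were HIF1A (-0.13; quantile 0.069, ratios 0.205, voom 0.21) and UQCRC1 (-0.27; ratios 0.068, voom 0.07), and in shISG20 cells HIF1A (-0.25; quantile 0.035, ratios 0.171, voom 0.176), ATP5F1B (-0.27; ratios and voom 0.154), RPS12 (-0.40; 0.026 and 0.023) and RPL12 (-0.41; 0.01 and 0.005). Values near 0 turned for CSF1R at 20% O2 (0.006; quality weights -0.001, voom -0.162, without 1 library -0.061 to 0.067, below 0 without shNTC replicate 2 or 3 or shISG20 replicate 3), H1-4 at 1% O2 (-0.022; 0.066 quantile, 0.049 ratios, 0.081 voom, without 1 library -0.184 to 0.154, above 0 without shNTC replicate 1, 0.059, or shISG20 replicate 3) and the interaction of MT-CO1 (0.027; without 1 library -0.068 to 0.1, below 0 without shNTC replicate 1, -0.063, or shISG20 replicate 2, -0.014, at 20% O2, or shISG20 replicate 3 at 1% O2).

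Other named gene results lost their call in 34 cases with no variance trend, 29 with only the groups compared, 21 with quantile normalization, 18 by voom, 17 with median-of-ratios size factors, 15 with no filter, 14 under the block and 11 with a pseudocount of 0.1. Depth limits low genes: ISG20 itself rested on 7 reads in shISG20 cells at 20% O2.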

Other observations

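Another 3 gene lists were written after the data were seen, so their p-values (limma's camera, adjusted over 15 tests) are no independent support. Members named by the rule were left out of tests and counts, 3, 5 and 3 in the order below, but not SLC7A11, whose value was seen. Genes of ribosome biogenesis in the nucleolus fell with hypoxia: 30 of 30 tested members fell and 0 rose in shNTC cells (median -1.57, adjusted p = 9.76e-12; adjusted p = 0.0148 with an estimated correlation) and in shISG20 cells (median -2.02, adjusted p = 1.1e-11; adjusted p = 0.0148 with an estimated correlation). FBL, the methyltransferase of ribosomal RNA, stood at -1.68 and -1.85, and NCL, nucleolin, at -1.21 and -1.33. The interaction was negative for 9 members and positive for 1 (adjusted p = 1.23e-06; adjusted p = 0.0412 with an estimated correlation), against 6 and 0 under quantile normalization. With the knockdown 4 rose and 0 fell at 20% O2 (adjusted p = 0.00144; adjusted p = 0.138 with an estimated correlation), and 1 rose and 9 fell at 1% O2 (adjusted p = 0.00125; adjusted p = 0.138 with an estimated correlation), against 1 and 5 with median-of-ratios size factors and 1 and 4 under quantile normalization.

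Targets of NRF2, the regulator of antioxidant genes, rose with hypoxia in shNTC cells, 12 of 17 up and 1 down (adjusted p = 3.56e-06; adjusted p = 0.0412 with an estimated correlation), with NQO1 at 2.03. In shISG20 cells 7 rose and 3 fell (adjusted p = 0.000902; adjusted p = 0.121 with an estimated correlation), against 12 and 1 with median-of-ratios size factors and 9 and 2 under quantile normalization. The interaction of the list was not called, with 2 positive and 2 negative members (adjusted p = 0.362), nor was the knockdown at 1% O2, with 4 down and 0 up (adjusted p = 0.342; 3 down and 1 up with median-of-ratios size factors), among them SLC7A11 (-0.97) and TXNRD1 (-0.63), or at 20% O2, with 1 up and 3 down (adjusted p = 0.63).

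Targets of YAP and TEAD had 4 of 15 up and 0 down with the knockdown at 1% O2 (adjusted p = 0.000321; adjusted p = 0.148 with an estimated correlation), with CCN2 at 0.72 and ANKRD1 at 0.66. They had 2 up and 1 down at 20% O2 (adjusted p = 0.839), and with hypoxia 2 up and 9 down in shNTC cells (adjusted p = 0.209; 2 and 6 with either scaling) and 2 up and 7 down in shISG20 cells (adjusted p = 0.789; 4 and 4 with median-of-ratios size factors, 3 and 5 under quantile normalization). The interaction was positive for 1 member, AXL at 1.09 (adjusted p = 0.00932 for the list; adjusted p = 0.313 with an estimated correlation).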
